A study of Homo sapiens with 6 samples.

How the data were processed

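The series is labelled as RNA sequencing of U251, a human glioblastoma cell line, with 3 untreated samples and 3 samples treated with 200 µM nootkatone, a sesquiterpenoid ketone of grapefruit, for 24 h. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with an NEBNext Ultra RNA kit. The submitters' processing notes name CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and the human build GRCh38, with no role or order.

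The deposited tables do not match those labels. Both tables list rat genes: 30560 of 31142 rows carry rat Ensembl identifiers, and the remaining 582 carry no Ensembl identifier. Chromosome names and protein descriptions are those of the rat, and the rat genome build is not given in the sources used here. The columns of each table are 3 with the names of the control samples and 3 whose names match no sample of the series. The 3 unmatched columns were not used in any step, since assigning them to nootkatone would have been a guess. The control-named columns were tied to the control samples by name only. Their values describe rat gene rows and are not attributed here to U251 cells. No column could be tied to a nootkatone sample, so the planned comparison of treated with untreated cells, its gene list tests and all of their alternatives were not run. The replicate numbers could not be used for pairing either.

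The authors deposited whole-number read counts per gene, not normalized. The authors also deposited FPKM values. These were taken as each count divided by the gene length and by 1 number per column. The median of that number over genes was 92.4%, 92.3% and 91.5% of the total count in control-named columns 1, 2 and 3. Whether it returns the deposited value of every gene was not checked. How that scaled total was obtained is not stated in the labels. Neither the library's strandedness nor the strand setting of the counting is given in the sources used here.

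Counts were scaled to CPM, the usual depth-normalised unit, with the TMM factors of edgeR 4.0.16 in R 4.3.3, over the 3 control-named columns alone. CPM is not divided by gene length, so rankings of genes or lists by CPM can partly reflect length. The factors lay between 0.996 and 1.00. A gene was called detected at a CPM of at least 1 in all 3 columns. Values are means ± SD over the 3 columns. Nothing in the labels says that the 3 came from separate cultures, so the spread may be technical. A count of 0 allows up to 3 counts per library, which corresponded to 0.199, 0.212 and 0.199 CPM in columns 1, 2 and 3. These floors cover counting error only, as the reads carry no molecular identifiers in the sources used here. Columns were compared with Pearson's r of log2 CPM over detected genes and with a chi-square of counts over genes with at least 20 summed counts. The biological coefficient of variation was estimated with edgeR and checked on simulated data: counts drawn for the 11997 detected genes with a true value of 0.05 gave back 0.0498.

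The 31 gene lists, written as human symbols, were fixed before the data were examined. They were matched to the table's rat names by spelling, ignoring case; 632 of 693 different symbols matched 1 row, 52 matched none and 9 matched several rows and were left out. Orthology was not checked beyond the shared name. The rule for named genes asked for the first gene of each list, which 29 lists had in the table, and for genes changed by treatment, which could not be determined. The genes named beyond the first of each list were chosen after their values were seen, as the most abundant, undetected or best known members of their list. The values of a few list members are not reported here, although they remain in the counts and medians of their lists. All values are levels within control-named columns, and no test between groups was made. Overlap between rows was taken from the start and end coordinates in the table, introns included, regardless of strand. An overlapped gene therefore need not share exons with the other row. The settings varied were the scaling, the detection threshold, the feature set, the depth and the columns included; those for the number of detected genes, the mitochondrial share and the list medians were chosen after seeing the data.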

Results

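The series set out to compare U251 glioblastoma cells exposed to nootkatone with untreated cells by RNA sequencing. Its labels describe 6 samples, 3 per group. The deposited tables, however, list rat genes, and only the 3 columns bearing the names of the control samples could be matched to a label. The comparison between nootkatone and control was therefore not made, and no gene is reported here as changed by nootkatone. What follows describes the 3 control-named columns as rat expression profiles of unstated origin.

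The 3 columns held 15106616, 14159479 and 15063919 counts. A total of 11997 genes reached at least 1 CPM in all 3. Protein-coding genes took 98.4% ± 0.0473 of the counts (SD, n = 3), and genes of the mitochondrial genome took 4.67%, 4.95% and 4.57% in columns 1, 2 and 3. Taken from summed FPKM, which divides counts by gene length, the mean mitochondrial share was 12.5%. Pearson's r of log2 CPM between columns, computed across genes, was 0.994 for each of the 3 pairs. Genes are not independent replicates, so this value describes the columns' similarity only. The biological coefficient of variation was 0.0563. The chi-square per degree of freedom between 2 columns was 3.56, 5.10 and 3.47 for the pairs 1 and 2, 1 and 3, and 2 and 3, so the columns differed by more than counting noise and were kept as 3 separate libraries.

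Fn1, which encodes fibronectin, stood at 8808 ± 156 CPM (SD, n = 3) and Vim, which encodes the intermediate filament vimentin, at 8058 ± 149 CPM. Spp1, the secreted phosphoprotein osteopontin, reached 6308 ± 287 CPM. Scd2, a stearoyl-CoA desaturase of rodents, reached 4965 ± 15.4 CPM. In the table's coordinates, Fn1 lies on chromosome 9 from 73196044 to 73264678. The gene list of extracellular matrix and mesenchymal genes had 30 of its 35 matched members detected, with a median of 68.7 ± 2.72 CPM. Within it, Tnc, the matrix glycoprotein tenascin C, stood at 2308 ± 96.4 CPM, whereas the fibrillar collagen gene Col1a1 stood at 11.2 ± 1.93 CPM and Col3a1 fell below the detection limit in at least 1 column, with a mean of 1.11 ± 0.209 CPM. All 17 YAP/TAZ target genes were detected, led by Ccn2, a matricellular protein gene, at 2631 ± 116 CPM.

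Nearly all matched proliferation genes were detected. Of the 36 genes of G2 and mitosis, 35 were detected, with a median of 110 ± 1.29 CPM. Top2a, which encodes the DNA topoisomerase of mitotic chromosomes, stood at 681 ± 20.1 CPM, and Mki67, a marker of cycling cells on chromosome 1 from 190496319 to 190522762, at 528 ± 16.9 CPM. The exception was Foxm1, a transcription factor of the mitotic program, with 0.615 ± 0.309 CPM; its row lies fully within the coordinates of another row. All 36 matched G1/S and replication genes were detected, with a median of 86.0 ± 2.95 CPM, among them Rrm2, a ribonucleotide reductase subunit, at 455 ± 11.7 CPM and the replicative helicase subunit Mcm2 at 198 ± 5.17 CPM. All 22 genes of homologous recombination and the Fanconi pathway were detected, with a median of 32.3 ± 2.03 CPM. The p53 target list had 22 of 24 members detected. Its first gene, the cell cycle inhibitor Cdkn1a, stood at 152 ± 12.1 CPM, and the p53 antagonist Mdm2 at 185 ± 6.33 CPM.

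Stress response lists were expressed unevenly. Endoplasmic reticulum chaperones were among the highest lists, with 23 of 24 genes detected, a median of 163 ± 2.39 CPM and Hspa5, which encodes the chaperone BiP, at 1877 ± 34.1 CPM. In the ATF4 list, 23 of 30 genes were detected. Ddit3, which encodes CHOP, stood at 57.5 ± 1.67 CPM, while Atf3, another stress-induced transcription factor, had 3 counts over the 3 columns. The NRF2 list had 16 of 21 genes detected: the quinone reductase gene Nqo1 stood at 635 ± 12.2 CPM and the haem oxygenase gene Hmox1 at 38.4 ± 2.29 CPM. The heat shock list had 16 of 17 matched genes detected, with Hspa8, a constitutive chaperone, at 1847 ± 22.9 CPM and Hspb1 at 0 counts in all 3 columns. The other 2 of its 19 listed symbols, HSPA1A, the first of the list, and HSPA1B, had no row of that name. The metallothionein gene Mt2A stood at 42.4 ± 1.62 CPM; only 3 of the 9 listed symbols had a row, of which 2 were detected.

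Lipid synthesis genes were detected nearly throughout. Of 25 cholesterol genes, 24 were detected, with a median of 81.3 ± 2.54 CPM. Sqle, squalene epoxidase, stood at 873 ± 7.68 CPM and Hmgcs1, an early enzyme of the pathway, at 281 ± 4.32 CPM. In the fatty acid list, 13 of 15 genes were detected, with a median of 170 ± 6.24 CPM; Fasn, fatty acid synthase, stood at 1210 ± 77.8 CPM and Scd at 225 ± 4.12 CPM. The LXR list had a median of 4.67 ± 0.997 CPM, with 8 of 11 genes detected and the cholesterol exporter Abca1 at 65.1 ± 2.75 CPM. Of 12 matched xenobiotic metabolism genes, 9 were detected. Cyp1a1, a cytochrome P450 induced by aryl hydrocarbons, stood at 4.42 ± 0.810 CPM, and Cyp1a2 and Ahrr had 0 counts. In the autophagy and lysosome list, 28 of 29 genes were detected, with the autophagy receptor gene Sqstm1 at 332 ± 9.19 CPM.

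Glycolysis and respiration were both represented. The hypoxia and glycolysis list had 23 of 25 genes detected, with Pkm, pyruvate kinase, at 3463 ± 85.0 CPM and the angiogenic factor Vegfa at 104 ± 3.26 CPM. Nuclear respiratory chain genes had 30 of 31 members detected and a median of 93.8 ± 6.65 CPM; the first of the list, Ndufa1, stood at 9.62 ± 1.21 CPM. All 13 mitochondrially encoded genes were detected, from Mt-atp8 at 10.5 ± 1.36 CPM to Mt-co1 at 10932 ± 575 CPM. This range is not corrected for gene length and need not reflect transcript abundance. Whether Mt-atp8 lost reads to an overlapping row was not tested. Every one of the 31 matched cytosolic ribosomal protein genes was detected, with Rplp0 at 2171 ± 86.5 CPM, as were all 25 matched ribosome biogenesis genes, with the nucleolar protein gene Ncl at 470 ± 18.1 CPM. Replication-dependent histones, whose mRNA normally lacks a poly(A) tail, had 3 matched genes and none detected, at a median of 0.156 ± 0.0741 CPM.

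Apoptosis and signalling genes varied widely. Of 18 pro-apoptotic genes, 15 were detected, with a median of 20.03 ± 2.11 CPM, and Pmaip1, which encodes the BH3-only protein NOXA, had 1 count over the 3 columns. Of 12 anti-apoptotic genes, 10 were detected, with Mcl1 at 213 ± 13.5 CPM and Bcl2 at 34.3 ± 0.257 CPM. In the ERK output list, 21 of 23 genes were detected; the cyclin gene Ccnd1 stood at 1253 ± 68.2 CPM and the immediate early gene Egr1 at 20.2 ± 5.52 CPM. All 18 FOXO target genes were detected, with Txnip at 15.1 ± 0.750 CPM.

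Inflammatory genes ranged from abundant to undetected. Cxcl10, a chemokine induced by interferon, reached 2805 ± 71.8 CPM and Ccl2, which attracts monocytes, 638 ± 4.69 CPM. The interferon list nevertheless had only 13 of 21 matched genes detected, and Isg15, a ubiquitin-like protein gene, had 0 counts in each column. In the NF-kB list 16 of 24 genes were detected, with Il6 at 10.9 ± 2.23 CPM and Ptgs2, Cxcl2, Cxcl3 and Ccl20 at 0 counts. Whether such 0 counts reflect silent genes or a counting effect was not tested.

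Of 14 genes of glioma stem and progenitor cells, 10 were detected, with a median of 13.2 ± 1.08 CPM. Of the 4 not detected, 1 had 0 counts in all 3 columns. The members named next all lay above the list median and do not stand for the list as a whole. Nes, an intermediate filament gene of neural progenitors, stood at 700.1 ± 25.3 CPM. The lineage transcription factor genes Sox10 and Sox2 stood at 331 ± 14.9 and 107 ± 9.30 CPM, and Cspg4 and Pdgfra, markers of oligodendrocyte progenitors, at 236 ± 18.3 and 181 ± 4.04 CPM. Among 14 astroglial genes, 9 were detected. S100b stood at 353 ± 7.93 CPM, Gfap, the astrocyte intermediate filament gene, at 5.14 ± 0.968 CPM, and the water channel gene Aqp4 had 0 counts. Of 16 matched markers of haematopoietic, endothelial and epithelial cells, 3 were detected, namely Cd14 at 72.3 ± 2.40 CPM, Cdh5 at 28.1 ± 1.92 CPM and Epcam at 22.4 ± 0.415 CPM. The leukocyte gene Ptprc had 0 counts.

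**Figure D1:**
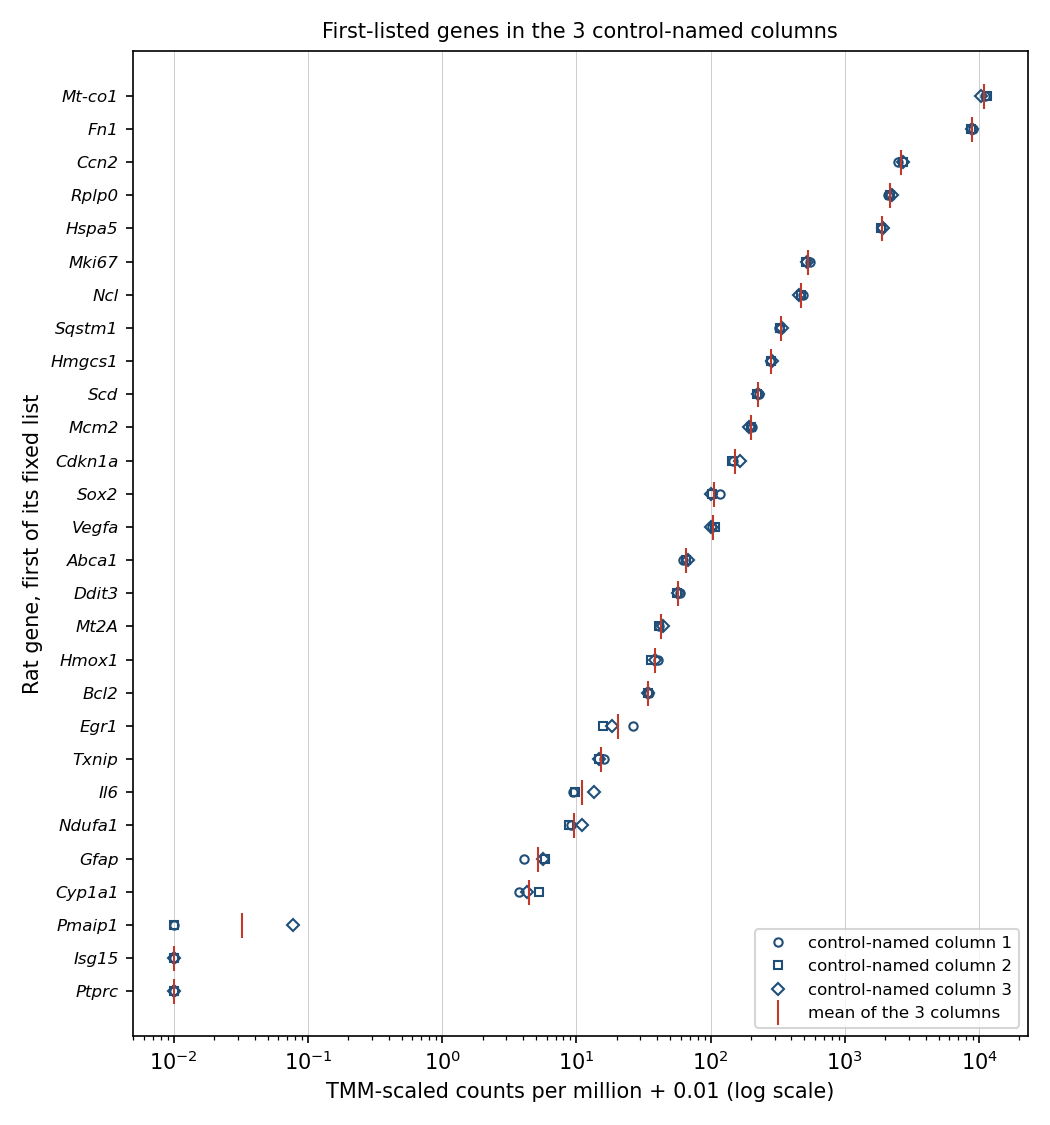
Level of the first-listed gene of 28 fixed lists in the 3 control-named columns, in TMM-scaled CPM with 0.01 added, on a logarithmic horizontal axis. Each open symbol is 1 column and each vertical red line is the mean of the 3; values run from 0 counts for Isg15 and Ptprc to a mean of 10932 CPM for Mt-co1, and the 3 columns lie farthest apart for Pmaip1, which rests on 1 count, and for Egr1, at 26.5, 15.9 and 18.4 CPM.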

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

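The alternatives for the number of detected genes, the mitochondrial share and the list medians were chosen after the data were seen. No paired analysis was possible because no column could be tied to a nootkatone sample, and the planned comparison and its alternatives were not run for the same reason. The number of detected genes stayed within 1.5 times the main 11997 under every setting tried: 12511 with a raw count of at least 10, 10206 at a CPM of at least 5, 11229 among protein-coding genes, 11997 with library totals in place of TMM factors, and 12094 to 12155 when 1 column was left out. The mitochondrial share of 4.73% became 12.5% when taken from summed FPKM, which divides by gene length; it was 4.69% among protein-coding genes and lay between 4.62% and 4.81% when 1 column was left out. For the 29 first-listed genes, library totals, size factors of the DESeq2 type computed in edgeR, and thinning to the smallest library moved none by more than the SD between columns. Scaling to protein-coding genes alone raised every first-listed gene with a count by nearly the same factor, to between 101.65% and 101.67% of its main value. Only for Hmgcs1 and Bcl2 was that common shift larger than the SD between columns. It says nothing particular about these 2 genes. All 31 list medians stayed within 1 SD with library totals. Leaving out 1 of 3 columns cannot move a mean of the 3 by as much as their SD, so it says nothing about the stability of a share, a gene or a list median. It took Pmaip1, which has 1 count, to between 0% and 150% of its value, and moved list medians to between 67.7% and 127%. Both ends of that range came from lists with medians near 0. These were the markers of other cell types, at 0.101 CPM, and the replication-dependent histones, at 0.156 CPM. The next widest list, the LXR targets, lay between 88.7% and 110%. Genes with a few counts cannot be told from 0 at this depth.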

Other observations

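Of the tests below, the comparison of overlap between near-zero and detected genes was chosen after the result was seen; the others were set out beforehand. The tables hold rat genes under human labels. If reads of human cells had been counted on a rat annotation, the rat major histocompatibility genes, which differ strongly in sequence from the human ones, were predicted to sum to under 10 CPM in each column. They summed to 261.0, 251.4 and 253.6 CPM in columns 1, 2 and 3, led by RT1-T24-1 at 89.0 ± 5.32 CPM and RT1-S3 at 76.9 ± 2.12 CPM (SD, n = 3), which argues against that explanation. That prediction rests on background knowledge of sequence divergence, not on an alignment. A single library deposited more than once is argued against by the lowest chi-square per degree of freedom between columns, 3.47. Whether the tables come from another experiment on rat cells, or the sample labels are wrong, was not tested and stays open, and so does the identity of the cells.

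Several genes of widely expressed functions were near 0. In the 16 lists with at least 90% of their matched members detected, 12 genes were not detected. They are called near-zero here, although Slc16a3, at 1.34 ± 0.488 CPM, only missed the detection rule and was not near 0. Of the 12, 5 lay over another row for at least 50% of their span from start to end, introns included. Among them were Foxm1, the secreted stress protein gene Manf, the lysosomal channel gene Mcoln1 and the transcription factor gene Junb. Whether exons overlapped was not tested. Among the 383 detected members of the same lists, 14 did (3.66%; Fisher's exact test, two-sided, p = 9.52e-05, with genes taken as independent, which was not checked). Reads lost to an overlapping gene row, as a hypothesis, were predicted to leave at least 50% of the near-zero genes overlapped in this way. The 5 of 12 came to 41.7% and missed that bound, so the explanation stays open. The overlapping rows were not all low: the row over Manf, Rbm15b, held 151 CPM and the row over Mcoln1, Pnpla6, held 44.1 CPM, while Tex52, over Foxm1, was at 0. The other 7, among them Hspb1 and Egln3, had a smaller overlap or none, and for them neither a counting effect nor silence of the gene was tested.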
